A study of Drosophila melanogaster with 19 samples.

How the data were processed

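MSL2 was immunoprecipitated with rabbit antibodies from crosslinked chromatin of whole adult flies, with IgG from preimmune rabbit serum as the control, per the labels' protocols. The series lists 19 samples that cover MSL1, MSL2, MSL3 and preimmune immunoprecipitations in several lines and both sexes. The MSL2 samples of wt males and M1[wt] males had peak lists and were compared. The other samples were not analysed here. Groups were taken from the sample titles, and each holds 1 listed sample.

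The submitters' processing notes name cutadapt, Bowtie2, Picard, deepTools and MACS2 and the genome builds dm6 and dm3, with no role or order. The caller's settings are not given in the sources used here. The sequence names and gene positions in the lists match dm6 (Release 6), the build of the gene table used here, and coordinates are printed 1-based in that build. Each deposited list has 20 columns without a header, in the layout that the irreproducible discovery rate (IDR) method writes for 2 replicate peak calls ranked by p-value. The tool is not named in the labels, and the labels do not say what the replicate calls are, so they were not treated as separate libraries. In the lists the authors deposited, the peak's own −log10 p is the lower of the values from the replicate calls in all 3799 and 3944 rows. Other columns the authors deposited hold the −log10 of the local and global IDR, and a score that is a scaled form of the global IDR. The smallest global value is 1.30 on the −log10 scale, so the lists hold peaks with a global IDR of 0.05 or less. The −log10 p is the authors' value for a peak and served to describe, rank and filter peaks within a list. It grows with sequencing depth, which is unknown here, so no change in strength between lists was computed.

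The design fixed before the data were examined ranked peaks by q and by fold enrichment. The lists as used here hold neither (their columns are filled with a placeholder), so −log10 p took their place, and the planned thresholds on q and fold were replaced by a global IDR of 0.01 or less, a global IDR of 0.001 or less, and a −log10 p of at least 50, chosen after seeing the data. Planned searches for GA-rich recognition sites and planned classes of promoter, UTR, exon and intron need a genome sequence and exon annotation, which were not used here. In their place summits were placed inside or outside genes and within 500 bases of a gene start or end, with 200 bases as the alternative.

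Peaks on chromosomes X, 2L, 2R, 3L, 3R and 4 were kept, and 11 wt and 9 M1[wt] peaks on other sequences were left out. The span of a chromosome ran from its first to its last annotated protein-coding or lncRNA gene, in place of its assembled length. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Peaks were called shared when they overlapped by at least 1 base. The chance level came from 1000 uniform random placements of the other list within each chromosome. X and autosomal peaks were compared by exact two-sided Fisher tests, and median strengths by two-sided permutation tests with 100000 resamples. Peaks next to each other are not independent, so these p-values describe the lists. For rank agreement each wt peak was paired with the strongest M1[wt] peak that overlapped it and had no partner yet. Random positions for the gene classes numbered 100000 per chromosome class.

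Gene symbols and positions came from an NCBI RefSeq gene table of the Release 6 assembly. A gene had a peak when a summit lay in it or within 1000 bases of it. The 12 gene lists were matched by symbol or by a synonym belonging to 1 gene, and 3 names that matched no gene or several were left out. The tests of the lists used protein-coding genes, with Benjamini-Hochberg adjustment over the 20 tests in each peak list. Each list was also set against 10000 random lists matched on chromosome class and on gene length in 10 classes.

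The genes named were fixed by a rule before the data were examined. They are those at the 10 shared X peaks and the 10 shared autosomal peaks with the best mean rank, those at the 5 strongest X and 5 strongest autosomal peaks of each list without a counterpart, all members of the dosage compensation list, and from each other list the members with the strongest peaks. RpS15Aa and the 9 genes of the list without peaks are named because they make up a small count. The Hsp genes are named to show which members of the control list had peaks. These choices were made after their values were seen. A peak was assigned to the genes that hold its summit, or else to the nearest gene start or end within 1000 bases.

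The overlap and gene assignment were tested on simulated data. Of the peaks of a simulated list made from the 3788 wt peaks, all that had been kept were found again (100%) and 0% of those removed were called shared. Of 200 real genes given a simulated peak, 100% were found, and 0.5% of 200 genes given none were assigned a neighbour's peak. Kept peaks were moved by less than the narrowest peak's width, new peaks were placed clear of all wt peaks, and gene peaks sat at gene midpoints. The outcomes were thus largely fixed by construction and show only that these steps ran as intended. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.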

Results

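The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for MSL2, the male-specific protein of the dosage compensation complex, in whole adult male Drosophila melanogaster flies aged 3 days. The complex binds the single male X chromosome and raises transcription of its genes. Of the 19 samples of the series, 2 entered the comparisons. They are the MSL2 sample of wt males and the MSL2 sample of males of the M1[wt] line, with 1 listed sample in each group. The series studies the N-terminus of MSL1, the subunit on which the complex assembles, and M1[wt] is named in it beside lines whose MSL1 carries deletions. The wt list held 3799 peaks and the M1[wt] list 3944. Each peak carried a −log10 p from each of 2 replicate calls, and the lower of the pair was used as its strength. The number of reads behind the peaks is unknown. The series lists no replicate samples of these groups, and whether the replicate calls come from separate libraries is not known. Every test over peaks therefore compares these lists and not the lines.

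The first comparison asked where MSL2 lay in each line. The X chromosome held 1615 of the 3788 wt peaks on the main chromosomes, a share of 42.6% with an exact Clopper-Pearson 95% interval of 41.1 to 44.2%. The M1[wt] list had 1595 of 3935 there, or 40.5% (39.0 to 42.1%). The X makes up 17.5% of the span covered by annotated genes on these chromosomes and carries 15.8% of their protein-coding genes. Peaks lay 3.51 times as densely on the X as on the autosomes in wt males, with 69.9 against 19.9 peaks per Mb, and 3.22 times as densely in M1[wt] males, with 69.0 against 21.5. The X shares of the lists did not differ past the threshold in an exact two-sided Fisher test (odds ratio 1.09, p = 0.0615).

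The strongest peaks of both lists were X-linked. The gene lncRNA:roX1, a noncoding RNA that is part of the complex, held the strongest peak in each, at X:3860712-3862761 in wt males (−log10 p of 15312) and X:3860651-3862750 in M1[wt] males (16196). All of the 20 strongest peaks of each list lay on the X (exact interval 83.2 to 100%). Among the 100 strongest the X held 83.0% in wt males and 87.0% in M1[wt] males, and among the 500 strongest it held 47.2% and 56.0%. X peaks were also wider, with a median width of 790 bases against 593 for autosomal peaks in the wt list and 837 against 721.5 in the M1[wt] list.

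**Figure D1:**
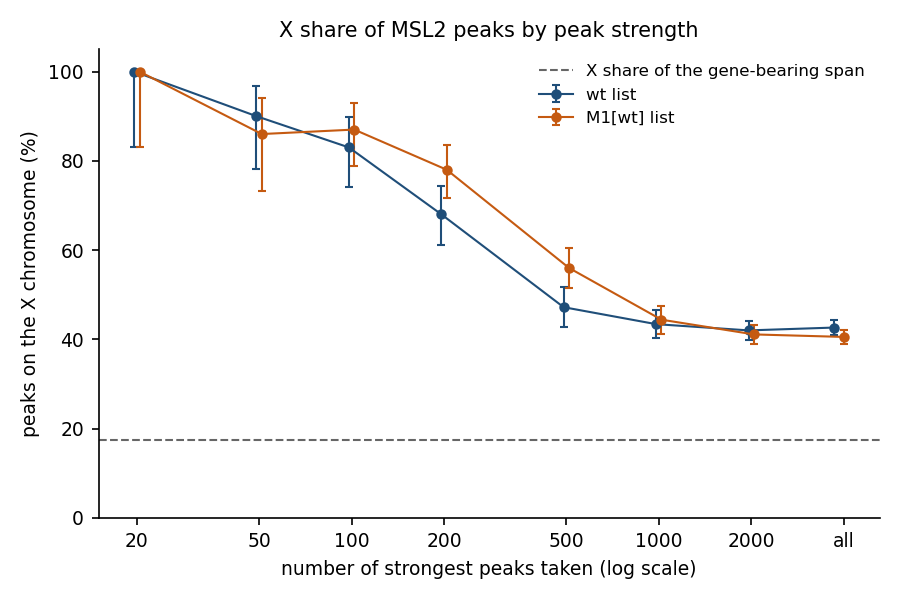
Share of peaks on the X chromosome (%, vertical axis) among a growing number of the strongest peaks (horizontal axis, log scale) in the wt and M1[wt] lists, with exact 95% intervals as bars. The dashed line is the X share of the gene-bearing span, 17.5%, and both lists fall from 100% at 20 peaks to 42.6% and 40.5% over all peaks.

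Over all peaks, the median strengths of X and autosomal peaks did not differ past the threshold. The −log10 p grows with read depth and males carry a single X, so like medians need not mean like enrichment. In wt males the median −log10 p was 22.2 on the X and 23.0 on the autosomes (two-sided permutation test of the medians, p = 0.338), and in M1[wt] males it was 36.6 and 34.6 (permutation test, p = 0.333). With the values of the first replicate call alone, a setting chosen after seeing the data, the wt median on the X was 0.882 times the autosomal one and passed the threshold (permutation test, p = 0.00521). The upper tail was held mostly by X peaks. A −log10 p of 500 or more was reached by 86 X and 18 autosomal peaks in wt males, and by 154 X and 44 autosomal peaks in M1[wt] males. The 99th percentile was 2913 on the X and 475 on the autosomes in wt males, and 3529 and 653 in M1[wt] males.

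The second comparison asked whether the lines shared their MSL2 sites. After lncRNA:roX1, the shared X peaks with the best mean rank lay in CG15247, in Rip11, an effector of the GTPase Rab11, in hep, a kinase of the JNK pathway, in CG34408, in the nucleoporin gene Nup153, in the phosphatase gene Pp2C1, in CG9132, in CG2186 and in PhKgamma, the catalytic subunit gene of phosphorylase kinase. All 10 of these summits lay inside the gene. The CG15247 peak, X:9874850-9876922, ranked 4 in wt males (−log10 p of 6075) and 2 in M1[wt] males (6107). The Rip11 peak, X:18636008-18640139, ranked 5 (5698) and 3 (5822). The hep peak, X:13079949-13081274, ranked 6 (5271) and 4 (5636). The peak in PhKgamma, X:11702742-11704269, ranked 12 (3394) and 16 (3561).

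On the autosomes the shared peaks with the best mean rank lay in CNBP, which encodes a zinc-finger protein that binds nucleic acids, beside Sox14, in Adf1, a transcription factor gene, beside nrv1, and in KCNQ, RasGAP1, Smg5, Adss and tara, with another beside CG7227. The CNBP peak, 2R:22936048-22937250, ranked 42 in both lists, with a −log10 p of 1221 in wt males and 1758 in M1[wt] males. The peak 295 bases from Sox14, 2R:23978230-23979329, ranked 41 (1319) and 50 (1607), and the Adf1 peak, 2R:6661730-6664033, ranked 37 (1404) and 67 (1349). The nrv1 summit lay 774 bases from the gene, in 2L:6786388-6788513. The RasGAP1 peak, 3L:9853890-9855379, ranked 106 (498) in wt males and 43 (1705) in M1[wt] males.

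Of the wt peaks, 75.4% on the X (exact 95% interval 73.2 to 77.5%) and 73.7% on the autosomes (71.8 to 75.5%) overlapped an M1[wt] peak by at least 1 base. Of the M1[wt] peaks, 72.8% on the X (70.5 to 75.0%) and 66.7% on the autosomes (64.7 to 68.6%) overlapped a wt peak. When the other list was placed at random within each chromosome 1000 times, the highest overlap on the X was 17.4% for wt peaks and 17.2% for M1[wt] peaks, and on the autosomes 4.51% and 4.32%. The chance medians were 14.4% and 14.5% on the X and 3.27% and 2.99% on the autosomes. The denser and wider X peaks thus overlap more often by chance, and a higher X share does not by itself show more sharing. The placements were uniform along each chromosome, while summits favoured gene ends, more so on the autosomes (given below). These chance levels may therefore be too low. The shared part of M1[wt] peaks was higher on the X by 6.12 percentage points (exact two-sided Fisher test, p = 4.52e-05). Chance overlap can add only peaks that are not shared otherwise, so the gap between the chance medians does not measure its part in this difference. That part was not tested. For wt peaks the difference of 1.74 points did not pass the threshold (exact test, p = 0.228). The wt difference passed it under other settings in opposite directions. It was 24.0 points among the 500 strongest peaks of each list (exact test, p = 8.37e-09). Those held 236 X and 264 autosomal peaks in wt males, but 280 and 220 in M1[wt] males. The same matches thus make different shares in each list, and the M1[wt] difference there was −0.487 points (exact test, p = 0.924). The 24.0 points therefore do not show more sharing on the X. The wt difference was −5.56 points with summits within 100 bases of each other (exact test, p = 0.000574) and −4.18 points within 250 bases (exact test, p = 0.0074). The M1[wt] difference was 1.49 points with summits within 250 bases of each other (exact test, p = 0.344), −0.28 points with summits within 100 bases (exact test, p = 0.869), and −0.35 points at a global irreproducible discovery rate of 0.001 or less (exact test, p = 0.891). Both lists were called against a male preimmune control, per the names the submitters gave the lists, so part of the overlap may come from it.

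Across 1153 pairs of shared X peaks the Spearman correlation of −log10 p between the lists was 0.809 (Pearson 0.888 on log10 values), and across 1555 autosomal pairs it was 0.752 (Pearson 0.782). Between the replicate calls inside the lists, over the same X peaks, it was 0.952 in wt males and 0.975 in M1[wt] males. Listed peaks had passed an IDR limit, which selects for agreement between those calls and can raise these values. They are therefore no yardstick for the correlation between the lists. Peaks are not independent replicates, so all of these correlations are descriptions. Summits of a pair lay a median of 20 bases apart on the X and 17 on the autosomes. Of the 100 strongest X peaks of each list, 75 overlapped one of the 100 strongest of the other. Of the 200 strongest, 152 wt and 150 M1[wt] peaks did.

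Several of the strongest peaks of each list overlapped no peak of the other. In wt males these lay on the X in sno, which encodes the nuclear protein Strawberry notch (X:13199114-13201903, rank 2, −log10 p of 7171), in Socs16D (X:17821266-17822465, rank 3, 6468), in the region where the autophagy gene Atg5, CG1677 and lncRNA:CR44357 overlap (X:7320233-7321453, rank 7, 5198), in CG2278 (rank 15, 3227) and in BTBD9 (rank 23, 1956). The nearest M1[wt] peak was 4881 bases away at sno, 3926 at Socs16D, 275 at Atg5, 1609 at CG2278 and 5481 at BTBD9. In M1[wt] males they lay in Stt3A, a subunit gene of oligosaccharyltransferase (X:21049929-21051587, rank 9, 4433), in the histone methyltransferase gene Hmt4-20 (X:649160-656668, rank 22, 2646), in the dopamine receptor gene Dop2R (X:20023829-20025388, rank 31, 1959), in Ns3 (rank 33, 1928) and in boi (rank 53, 1552). The nearest wt peak was 122433 bases away at Dop2R, 1123 at Hmt4-20, 802 at Stt3A, 394 at Ns3 and 343 at boi.

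Autosomal peaks of this kind were weaker. In wt males they lay in l(3)neo38 (3R:11777107-11780665, −log10 p of 969), in kay, the Drosophila Fos gene (3R:29771960-29774575, 774), 84 bases from msl-1 (2L:18688284-18689934, 471), in crol (468) and beside the proton pump subunit gene Vha13 (447). In M1[wt] males they lay beside CG7601 (3R:29736345-29737431, 733), in Trp1 (536), beside CenG1A (464), in shep (322) and beside ecd (299). The state of the msl-1 locus in M1[wt] flies is not given in the sources used here, so the missing counterpart at msl-1 does not tell of MSL2 binding there. Of the 20 strongest X peaks, 4 in the wt list (20.0%, exact interval 5.73 to 43.7%) and 1 in the M1[wt] list (5.00%, 0.127 to 24.9%) had no counterpart. Of the 400 strongest X peaks, 36 in the wt list (9%, exact interval 6.38 to 12.2%) and 38 in the M1[wt] list (9.5%, 6.81 to 12.8%) had no counterpart. A peak missing from a list is not a measurement of lost binding, because the lists hold only peaks that passed in both replicate calls and no signal between peaks was used here.

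**Figure D2:**
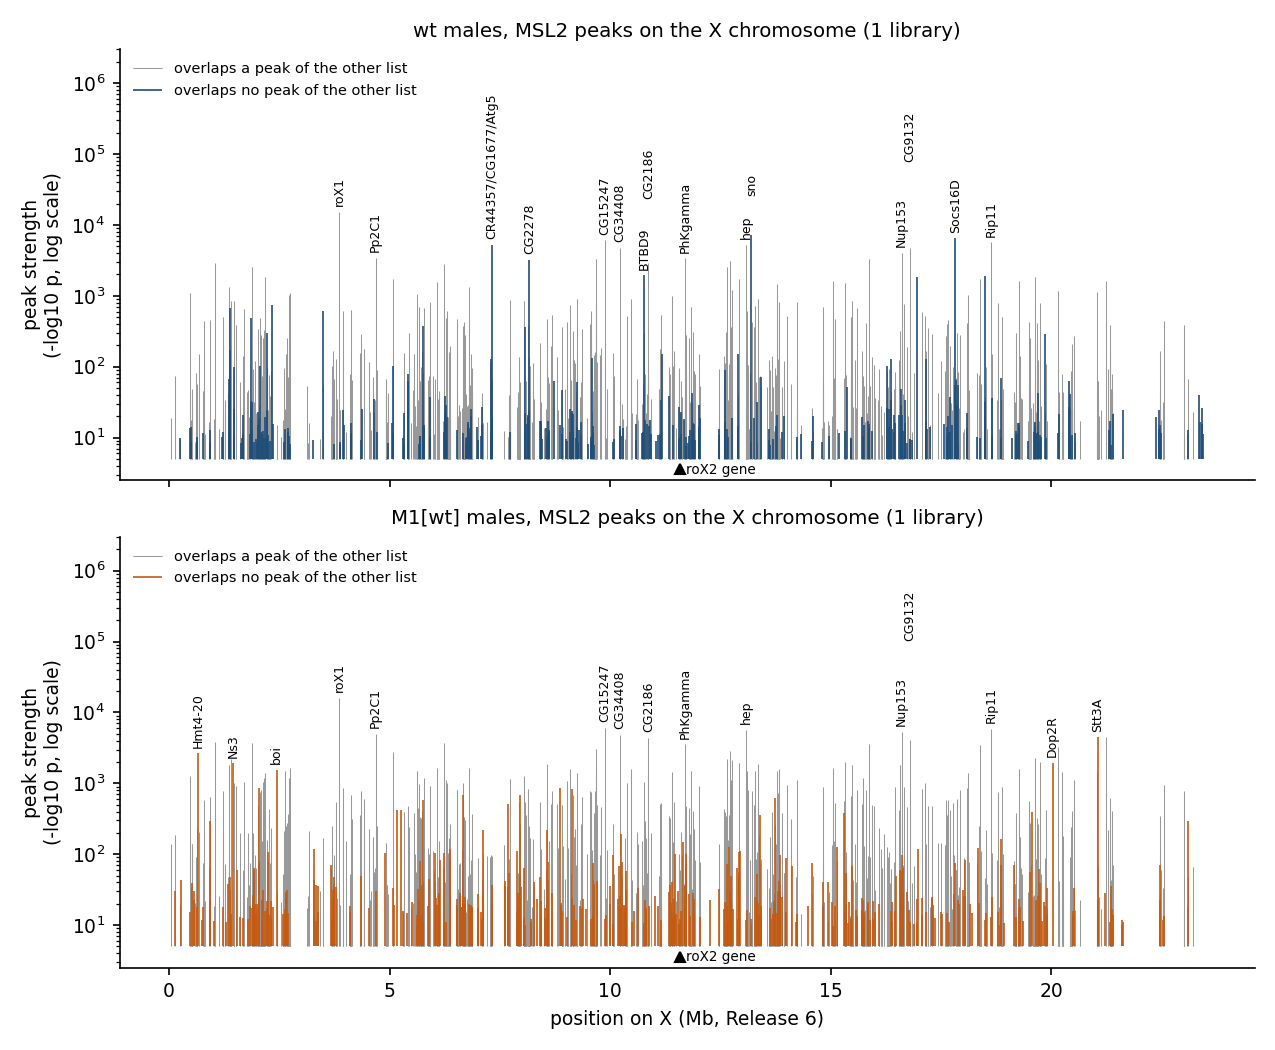
MSL2 peaks along the X chromosome (position in Mb, Release 6) against their −log10 p (log scale). The top panel is wt males and the bottom panel M1[wt] males, 1 listed sample each. Grey lines are peaks that overlap a peak of the other list and coloured lines those that do not. The named genes are the 10 shared peaks with the best mean rank over both lists and the 5 strongest without a counterpart in that list, the triangle marks the roX2 gene, and lncRNA:roX1 is the highest line in both.

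**Figure D3:**
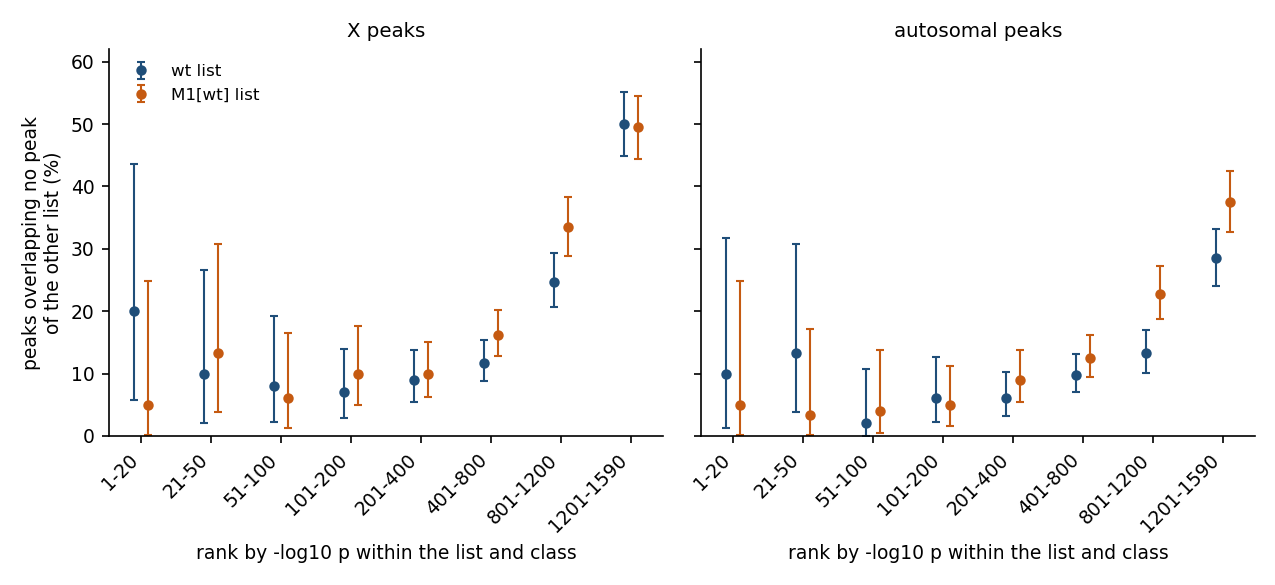
Share of peaks that overlap no peak of the other list (%, vertical axis) by rank within the list and chromosome class (horizontal axis, 1 is strongest) for X peaks (left) and autosomal peaks (right), with exact 95% intervals. On the X the share is 20.0% in the wt list and 5.00% in the M1[wt] list at ranks 1 to 20, 9% and 10.0% at ranks 201 to 400, and 50.0% and 49.5% at ranks 1201 to 1590.

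The genes of the dosage compensation complex and its partners were looked up one by one. Besides lncRNA:roX1, a peak lay in or within 1000 bases of mof, the X-linked acetyltransferase gene (−log10 p of 64.8 in wt males and 121 in M1[wt] males), of mle, the RNA helicase gene (28.1 and 28.0), and of JIL-1, a histone kinase gene (22.6 and 23.9) in both lists. The gene msl-1 (of unknown state in M1[wt] flies) had a peak in wt males alone, and Clamp, which encodes a zinc-finger protein that binds GA repeats, had one in M1[wt] males alone (52.6). Neither list had a peak at msl-2 or msl-3. Of the 6 protein-coding autosomal members, 3 had a peak in each list, a share that did not pass the threshold (exact two-sided Fisher test, adjusted p = 0.288 in wt males and 0.309 in M1[wt] males). At lncRNA:roX2 (X:11579065-11580432) the wt list held an interval 9633 bases wide, X:11572824-11582456, with its summit in the gene and a −log10 p of 22.2, at rank 1928. No M1[wt] interval overlapped lncRNA:roX2, and the nearest ones, X:11572887-11573506 and X:11583963-11585137, lay on either side of it. Whether this wide interval, its low strength and rank, and its absence from the M1[wt] list come from the peak calling or from the flies is not known.

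The third comparison asked how the peaks lay relative to genes. X summits lay mostly within gene bodies and autosomal summits often close to a gene end. In wt males 88.7% of X summits (exact 95% interval 87.1 to 90.2%) and 65.8% of autosomal summits (63.8 to 67.8%) lay inside a protein-coding or lncRNA gene, against 75.3% and 69.0% of random positions (exact two-sided Fisher test of X against autosomes, odds ratio 4.09, p = 3.16e-63). The shares in M1[wt] males were 88.5% and 65.3% (exact test, odds ratio 4.08, p = 8.95e-65). Within 500 bases of a gene start or end lay 37.0% of X and 57.5% of autosomal summits in wt males (exact test, odds ratio 0.434, p = 7.26e-36), and 33.5% and 57.1% in M1[wt] males (exact test, odds ratio 0.379, p = 2.57e-48), against 15.6% and 17.5% of random positions. Strand and exons were not used here, so start and end of a gene, exons and introns are not told apart.

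**Figure D4:**
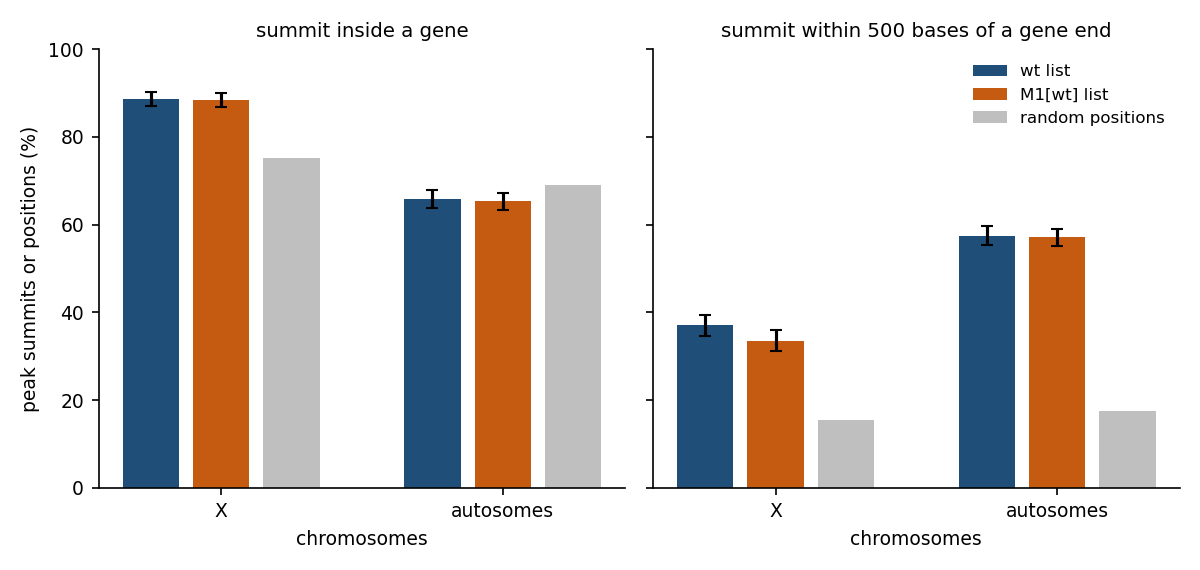
Share of peak summits (%, vertical axis from 0) inside a protein-coding or lncRNA gene (left) and within 500 bases of a gene end (right), for X and autosomes, in the wt list, the M1[wt] list and 100000 random positions per class; bars carry exact 95% intervals for the peaks. X summits lie inside genes in 88.7% and 88.5% of cases, and autosomal summits near gene ends in 57.5% and 57.1%.

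The fourth comparison asked which groups of genes carried peaks. Of 2192 X-linked protein-coding genes, 1179 (53.8%) had a peak in or within 1000 bases of the gene in wt males and 1140 (52.0%) in M1[wt] males, and 1012 (46.2%) had one in both. Of 11719 autosomal genes, 2617 (22.3%) and 2817 (24.0%) had one, and 2142 (18.3%) had one in both. The lists of genes were fixed before the data were examined, and p-values are exact two-sided Fisher tests against the other genes of the same chromosome class, adjusted over 20 tests per peak list.

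Ribosomal protein genes carried peaks more often than other genes on the X and on the autosomes. On the X all 14 had a peak in wt males (exact test, adjusted p = 0.00127) and 13 in M1[wt] males, where RpS15Aa had none (exact test, adjusted p = 0.00986). On the autosomes 32 of 78 had one in wt males (41.0% against 22.2% of other genes; exact test, adjusted p = 0.00127) and 34 in M1[wt] males (43.6% against 23.9%; exact test, adjusted p = 0.0015). The strongest in wt males were at RpL7A on the X (−log10 p of 365), RpL26 on 3L (330) and RpL32 on 3R (312), with 804, 405 and 316 in M1[wt] males. These calls rest on summits beside the genes as well as in them. With summits inside the gene alone, 8 of 14 on the X had a peak in each list (exact test, adjusted p = 0.553 in wt males and 0.412 in M1[wt] males). On the autosomes 8 and 11 of 78 did (exact test, adjusted p = 0.849 and 0.455), so no ribosomal protein call passed. The genes of DNA-binding and insulator proteins on the autosomes also carried peaks more often, 11 of 16 in wt males (exact test, adjusted p = 0.00127) and 12 in M1[wt] males (exact test, adjusted p = 0.000491), the strongest in wt males at pzg (285), pita (178) and Trl (99.97), the gene of GAGA factor. A pair of neighbouring members was counted from the same wt peak, 3R:9258301-9258555, while the test treats genes as independent. Clamp belongs to this list and to the dosage compensation list. Heat shock and highly transcribed control genes had a peak at 11 of 21 autosomal members in each list (exact test, adjusted p = 0.00997 and 0.0309). Among them were betaTub56D (176 in wt males, 285 in M1[wt] males), Pgk (103 and 264) and eEF1alpha1 (77.5 and 182). Of its Hsp genes, Hsp22, Hsp23, Hsp26, Hsp70Ab, Hsp70Ba and Hsp70Bb had a peak in neither list. Hsp68 had one in both (22.2 and 31.3), Hsp83 in wt males alone (23.7), and Hsp27 (63.3) and Hsp70Aa (11.3) in M1[wt] males alone. With summits inside the gene alone, 3 of 21 members in wt males and 5 in M1[wt] males had a peak (exact test, adjusted p = 0.62 and 0.2).

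None of the 9 X-linked genes of sex-restricted or larval expression, which are the yolk protein genes Yp1, Yp2 and Yp3, the chorion genes Cp36, Cp38, Cp7Fa, Cp7Fb and Cp7Fc, and Lsp1alpha, had a peak in either list, against 54.0% of other X genes in wt males (exact test, adjusted p = 0.00472) and 52.2% in M1[wt] males (exact test, adjusted p = 0.00885). These tests treat the genes as independent, but they form 4 runs of neighbours. The chorion genes lie in X:8470888-8483311, and Yp1 lies beside Yp2 in X:10050951-10055498. When the list was moved as a block to all 2192 positions along the X gene order, a test chosen after seeing the data, 36 positions in wt males and 32 in M1[wt] males held as few (exact one-sided test, unadjusted p = 0.0164 and 0.0146). Among 10000 random lists matched on gene length, the count of this list stood at percentile 0.085 in wt males and 0.16 in M1[wt] males, that of ribosomal protein genes at 100 in both, that of the heat shock and control list at 99.9 and 99.8, and that of the insulator list at 99.97 and 99.99. In M1[wt] males the calls of X-linked ribosomal protein genes and of the heat shock and control genes no longer passed at a global irreproducible discovery rate of 0.01 or less (exact test, adjusted p = 0.0876 for both) or 0.001 or less (exact test, adjusted p = 0.156 and 0.292). At 0.001 or less the 9 X-linked genes no longer passed in either list (exact test, adjusted p = 0.124 in wt males and 0.155 in M1[wt] males). Counting only summits inside the gene, the test of the insulator list alone kept its call in both lists (exact test, adjusted p = 0.00931 in wt males and 0.0128 in M1[wt] males), and the classic X-linked genes passed in wt males (15 of 20; exact test, adjusted p = 0.0181). At a −log10 p of at least 50, a limit chosen after seeing the data, the calls that passed in each list were those of autosomal ribosomal protein genes (exact test, adjusted p = 0.000223 in wt males and 0.0038 in M1[wt] males) and insulator genes (exact test, adjusted p = 0.000743 and 0.000305).

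The other lists did not pass the threshold in either peak list. Classic X-linked metabolic and visible marker genes had a peak at 16 of 20 members in wt males (80.0% against 53.5%; exact test, adjusted p = 0.0752) and 15 in M1[wt] males (exact test, adjusted p = 0.106), the strongest at arm, the Drosophila beta-catenin gene (2534 and 3661), at Ubi-p5E (488 and 1127) and at the clock gene per (256 and 273). Of 29 testis germline genes, all autosomal, 2 had a peak in each list, mia (83.8 and 66.4) and achi (17.7 and 17.1) (exact test, adjusted p = 0.128 and 0.0955). Of 14 accessory gland genes, 1 had a peak, Acp95EF (51.2 and 32.2; exact test, adjusted p = 0.551 and 0.351). Among neuron and photoreceptor genes, 9 of 13 on the X had a peak in each list (exact test, adjusted p = 0.621 and 0.416), the strongest in wt males at rdgB (1458 and 1473), rdgA (424 and 1091) and norpA (286 and 791), and of 13 on the autosomes 1 had a peak in wt males, Syt1 (29.8), and 0 in M1[wt] males (exact test, adjusted p = 0.551 and 0.106). Sex determination genes had a peak at 5 of 14 members in wt males and 7 in M1[wt] males, the strongest at dsx (248 and 291) and ix (127 and 220), with X-linked peaks at Sxl, the switch gene of sex determination, that lay apart in the lists (27.0 at X:7098007-7098264 in wt males and 45.3 at X:7095558-7096245 in M1[wt] males) (exact test on the autosomes, adjusted p = 0.288 and 0.106). Muscle genes had a peak at 6 of 19 members in each list, the strongest in wt males at sls (16.0 and 39.0) and Tm1 (15.3, and 58.0 at a separate M1[wt] peak), with an adjusted p of 1 in both chromosome classes (exact test). Fat body and haemolymph genes had a peak at 4 of 14 members in each list, among them Mtp (80.4 and 128) and Lsd-2 (69.0 and 152), with adjusted p-values from 0.351 to 1 (exact test). Its members without a peak include Yp1, Yp2 and Yp3, which also belong to the list of sex-restricted or larval expression above.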

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

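Peaks outside the main chromosomes entered no comparison above. The wt list holds 11 of them and the M1[wt] list 9, on 10 and 7 sequences. Of these, 3 and 4 lie on sequences of the Y chromosome and 7 and 5 on sequences without a place in the assembly. Their median −log10 p was 19.9 in wt males and 46.8 in M1[wt] males, and the highest were 166 and 275. They stand out as signal called over the preimmune control in sequence that the gene table used here does not cover, and no explanation was tested.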

How the results depend on the processing

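Among the alternative settings below, limits on the global IDR, the −log10 p limit, the use of 1 replicate call and the distance of 200 bases were chosen after seeing the data. The other alternatives were chosen before. Of the main settings, the ranking by −log10 p, the chromosome span and the gene classes replaced planned ones, as described above. Depth is unknown, so its effect could not be examined, and the cause of the moves below was not tested unless stated. Planned limits on q and fold, and all settings of the GA-rich site search and of the exon classes, were not run, because the lists as used here hold no q or fold and no genome was used. Merging overlapping intervals changed nothing, since none overlap. Taking as many peaks as the shorter list holds moved no share beyond its interval. The Spearman correlations moved by less than 0.05 under their alternatives. No paired analysis was possible because each group has 1 listed sample and the nature of the replicate calls is not given.

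The X share of peaks was 53.4% of covered bases in wt males and 49.4% in M1[wt] males, 47.2% and 56.0% of the 500 strongest peaks, 40.8% of wt peaks at an IDR of 0.001 or less, and 42.1% of M1[wt] peaks at a −log10 p of at least 50. Wider X peaks account for the share of covered bases, with mean widths of 1089 against 706 bases in wt males and 1193 against 832 in M1[wt] males.

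The shared part of wt peaks, X then autosomes, was 79.3% and 80.0% at an IDR of 0.001 or less, 85.5% and 84.7% at a −log10 p of at least 50, 80.1% and 56.1% of the 500 strongest, 65.9% and 65.5% with a reciprocal overlap of 50%, 58.3% and 63.8% with summits within 100 bases and 64.0% and 68.2% within 250, and for autosomes 77.1% at an IDR of 0.01 or less. Of M1[wt] peaks it was 67.7% on the X at an IDR of 0.001 or less, 56.5% and 53.5% at a −log10 p of at least 50, 66.8% on the X among the 500 strongest, 66.7% and 60.9% with a reciprocal overlap of 50%, 59.0% and 59.3% within 100 bases and 64.8% and 63.3% within 250. With both lists limited, a match can be lost because its partner falls below the limit.

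The X minus autosome difference in shared wt peaks was 24.0 points among the 500 strongest, and it reversed to −5.56 points with summits within 100 bases and −4.18 within 250, all 3 past the threshold. The 24.0 points rest on unequal numbers of peaks, 236 X and 264 autosomal in wt males against 280 and 220 in M1[wt] males. For M1[wt] peaks it reversed to −0.35 points at an IDR of 0.001 or less, −0.487 among the 500 strongest and −0.277 within 100 bases, and it no longer passed at 3.06 points with a −log10 p of at least 50 and 1.49 within 250 bases. The ratio of X to autosomal median strength in wt males ran from 0.882 to 0.973 with the values of 1 replicate call, and the first call alone passed the threshold (permutation test, p = 0.00521).

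Summits inside genes in wt males were 86.0% on the X and 57.2% on autosomes at an IDR of 0.001 or less, 86.6% and 50.1% at a −log10 p of at least 50, and 62.8% on autosomes at an IDR of 0.01 or less. In M1[wt] males they were 85.6% and 56.4% at a −log10 p of at least 50, and on autosomes 63.2% and 59.2% at an IDR of 0.01 and 0.001. Summits within 500 bases of a gene end in wt males were 42.3% and 67.1% at an IDR of 0.001 or less, 43.0% and 70.3% at a −log10 p of at least 50, and 61.5% on autosomes at an IDR of 0.01 or less. On autosomes in M1[wt] males they were 59.3% at an IDR of 0.01 or less, 62.4% at 0.001 or less and 64.2% at a −log10 p of at least 50. Within 200 bases lay 16.2% of X and 42.8% of autosomal summits in wt males and 14.4% and 42.1% in M1[wt] males. Under all of these settings the X share was above the autosomal share inside genes and below it near gene ends.

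Of the list tests, 5 passed in each peak list. With summits inside genes alone 2 passed in wt males and 1 in M1[wt] males, with a −log10 p of at least 50 it was 2 and 2, at an IDR of 0.01 or less it was 5 and 3, and at 0.001 or less 4 and 2.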

Other observations

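Weaker X peaks lay around the strongest ones. Of 1415 wt X peaks below the 200 strongest, 843 (59.6%) had their summit within 20000 bases of a summit of the 200, against 385 at the median of 1000 random placements. In M1[wt] males 805 of 1395 (57.7%) did, against 394. On the autosomes 277 of 1973 wt peaks (14.04%, against 133 at random) and 316 of 2140 M1[wt] peaks (14.8%, against 141) did. The small chromosome 4 carried 18 peaks in wt males (14.2 per Mb) and 32 in M1[wt] males (25.2 per Mb).

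The test of the highest scores for strong unmatched peaks and that of broad regions for weaker X peaks were set after those peaks had been seen, and the other tests in this part before their results; tests of the calling limit and of a line difference are left out, because the former counted the peaks that define the pattern and the latter could not tell a line difference from its absence. Among the 400 strongest X peaks, 9% of wt and 9.5% of M1[wt] peaks had no counterpart. A caller that fails at the very highest scores is not the whole cause, because 69 of the 74 peaks lay below rank 20, but for the others it stays open: 5 of 40 peaks at ranks 1 to 20 and 69 of 760 at ranks 21 to 400 had no counterpart (exact Fisher test, p = 0.406). Shifted peak edges remain open for some of them: 12 of 36 wt and 14 of 38 M1[wt] peaks had a peak of the other list within 1000 bases, 33.3% and 36.8%, with an upper bound of 54.0%, while the others had none. No chance level was computed for such neighbours. X peaks lie densely, so part of these neighbours may be there by chance. A difference in binding between the lines also stays open and was not tested, since each line has 1 listed MSL2 sample.

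For the weaker X peaks near strong ones, a limit of 3000 bases for broad regions split into several peaks was set first and dropped, because single intervals were up to 11672 bases wide. Broad regions of up to 12000 bases would leave no excess beyond that distance, but between 12000 and 20000 bases there were 199 peaks in wt males and 196 in M1[wt] males, at least 1.42 times as many as at random (upper 95% limits of the random counts 159 and 158), and wider regions stay open. Clustering of all X genes would give as many peaks placed at random inside X genes, and the observed number was at least 1.83 times that. Genes held 75.3% of random X positions, so this placement differed little from a uniform one (436 against 385 at the median in wt males). Clustering of the genes that carry peaks was not modelled and stays open. Binding around the strongest X sites that is absent from autosomes would give a higher ratio on the X, and the ratios overlapped in their random spread: 2.19 on the X and 2.08 on the autosomes in wt males, 2.04 and 2.24 in M1[wt] males, a lowest difference of −0.198. Whether the X differs from the autosomes in this respect therefore stays open.

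Autosomal peaks made up over 50% of each list. Peaks near the calling limit would leave under 25% among the 500 strongest, and the autosomal share there was 52.8% in wt males and 44.0% in M1[wt] males (lower exact bound 39.6%), which argues against that cause. Unspecific recovery of highly transcribed genes would give peaks at such genes more often than at others of like length. Of 99 autosomal ribosomal protein, heat shock and control genes, 43 had a peak in wt males and 45 in M1[wt] males. The medians of 10000 random lists matched on gene length were 16 and 18, which puts both counts at percentile 100. These genes are those of the list tests above. MSL2 binding beside them would give such counts too, and no transcript levels were used here. The counts therefore cannot tell unspecific recovery from binding. Summits lay inside 8 of 78 ribosomal protein genes and 3 of 21 heat shock and control genes in wt males. In M1[wt] males they lay inside 11 and 5. Counted this way, neither group passed the threshold (exact test, adjusted p = 0.849 and 0.62 in wt males, 0.455 and 0.2 in M1[wt] males). The 99 genes are few beside the 2173 and 2340 autosomal peaks, and other highly transcribed genes were not counted. Whether unspecific recovery covers any of those peaks therefore stays open, and no biological explanation was tested.

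The replicate calls inside each list differed in level. The first call had the higher −log10 p at 81.9% of wt peaks and at 21.3% of M1[wt] peaks.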
